A study of Mus musculus with 12 samples.

How the data were processed

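RNA had been taken from the hippocampus of 4-month-old male mice, 3 transgenic for APP/PS1 and 3 wild-type (WT) littermates. Per the labels, these mice gave stranded total RNA libraries and small RNA libraries, 3 of each kind per genotype and 12 in all, sequenced on an Illumina HiSeq instrument. The replicates of each kind were taken to be separate animals, and no label ties a small RNA column to the mouse of a total RNA library. The WT libraries are numbered 1, 2 and 4 and the APP/PS1 libraries 1, 2 and 3. Circular RNA values were not analysed here.

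The total RNA table holds whole-number estimated counts per gene symbol for each library, as deposited. The submitters' processing notes name HISAT2, StringTie and DESeq, without versions or roles, and the genome build mm10. The counting step, the annotation, the strand setting and the filters are not given in the sources used here. Summed over the 6 total RNA libraries, the value 4 occurred 1817 times, the value 5 occurred 1346 times and the value 8 occurred 1201 times, against 897 times for the value 3 and 624 times for the value 6. From these low values alone 1 sequenced fragment was taken to stand for about 4 of the estimated counts. The read length and the conversion used are not given in the sources used here, so the depth in fragments is uncertain. The estimated counts were used as whole numbers as deposited, without further rounding. The table lists 24736 symbols, of which 24076 (97.3%) matched a RefSeq table of assembly GRCm38.p6, which is the same build as mm10 and gave the coordinates. The table holds no genes encoded by mitochondrial DNA.

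The small RNA table holds raw counts per mature miRNA in 6 columns, as deposited, for 1978 miRNAs. The tools named in the submitters' processing notes are the same for both kinds of library, and which of them made the miRNA counts is not given. The columns of this table carry bare names that equal the titles of the total RNA libraries, so each small RNA column was assigned to its genotype only and is called by its heading. There were 26 miRNAs with a mean count over 20 whose counts equalled those of another miRNA in every column, as for miR-486a-5p and miR-486b-5p, and such members cannot be separated.

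Total RNA libraries summed to 120958765 to 146904552 estimated counts, whose number in fragments is uncertain. Small RNA columns summed to 15593728 to 21631169 counts. With these depths the spread between libraries, not counting error, set the precision for abundant features. The biological coefficient of variation was 26.5% for the total RNA libraries and 26.2% for the small RNA columns. Without APP/PS1 replicate 3, a library that stood apart, it was 19.7% for total RNA.

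APP/PS1 libraries were compared with WT libraries in each table by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, edgeR's default expression filter and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter kept 18060 genes and 703 miRNAs. Expression is given as CPM, counts scaled to TMM-adjusted library size, as mean ± SD over 3 libraries, and log2 fold changes are APP/PS1 over WT with a standard error (SE) derived from the fold change and the quasi-likelihood F statistic. Before the data were examined, 37 gene lists and 9 miRNA lists were fixed, along with the tests, the other settings to be tried and the rule for named features. The 35 gene lists and 9 miRNA lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 3, and again with the correlation estimated per list and with fry. A list of cerebellar genes and a list of medulla, pons and spinal cord genes were added after seeing the data.

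The rule for named genes took genes with sequence in the construct, App and Prnp among them, then 10 genes per direction with the largest change among those past the threshold with no overlap between groups and a mean count of at least 20. Where fewer passed, the genes with the smallest unadjusted p filled the places. For each list it took up to 4 members past the threshold or otherwise the 2 members with the smallest p. The rule for miRNAs was the same with 8 per direction. Some genes that the rule took are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

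The other settings were other size factors, other count filters, DESeq2 1.42.0, limma-voom, an unadjusted p under 0.05 with a 2-fold change, a surrogate variable from sva 3.50.0, the replicate number as a block, and leaving out each library in turn. Division of the estimated counts by 4, sample quality weights, an estimated correlation with 1 library left out and the added lists were chosen after seeing the data. The edgeR procedure was tested on simulated data drawn from the real means, library sizes and dispersions. Of 18060 simulated genes, 100 changed 2-fold and 100 changed 4-fold; 35% and 89% of them were recovered, and 4 of 128 calls were false. With 0.1 of the fitted dispersion the recovered shares were 96% and 100%, and 17 of 213 calls were false. For 703 simulated miRNAs, 43.3% of 30 changed 2-fold and 100% of 30 changed 4-fold were recovered, with 2 of 45 calls false. In each simulation the changed features were drawn only from those above a minimum mean count. Recovery at low counts was therefore not tested. A test of predicted miRNA target sites was planned and needs 3′ untranslated sequences, which were not used here.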

Results

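Hippocampal transcripts of 4-month-old APP/PS1 mice, which carry a chimeric amyloid precursor protein with the Swedish mutation, were compared with those of WT littermates. Protein-coding and other long transcripts were measured in 6 total RNA libraries and mature miRNAs in 6 small RNA columns, 3 per genotype in each. The total RNA libraries held 120958765, 133984317 and 134147448 estimated counts for APP/PS1 replicates 1, 2 and 3, and 123759886, 125651066 and 146904552 for WT replicates 1, 2 and 4. The small RNA columns headed APP1, APP2 and APP3 held 15593728, 16261137 and 17033557 counts, and those headed WT1, WT2 and WT4 held 21631169, 18071167 and 16557707. Malat1, a nuclear long noncoding RNA, took 1.56% of the estimated counts of the total RNA libraries, and miR-9-5p, a miRNA abundant in neural tissue, took 13.8% of the small RNA counts.

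The first comparison asked whether the transgenic libraries carry the transcripts of the construct. App, which encodes the amyloid precursor protein (chromosome 16, 84952666 to 85175255, mm10), stood at 3194 ± 260 CPM in APP/PS1 and 1550 ± 29.1 CPM in WT (SD, n = 3 each), a log2 fold change of 1.04 (SE 0.09). Prnp, the prion protein gene whose promoter and flanking sequences drive such constructs (chromosome 2, 131909928 to 131938436), stood at 1039 ± 113 CPM and 504 ± 26.2 CPM, a log2 fold change of 1.04 (SE 0.10). All 3 APP/PS1 values of App and of Prnp lay above all 3 WT values. With edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p was 0.117 for App and 0.165 for Prnp over all 18060 genes tested, so neither passed over all genes. Adjusted over the list alone, p was 3.9e-05 for App and 4.1e-05 for Prnp in the same edgeR test. Without APP/PS1 replicate 3, edgeR's adjusted p over all genes was 0.0136 for App and 0.0172 for Prnp, and with DESeq2 it was 7.1e-22 and 3.1e-14. Over the settings tried it reached 0.906 for App, without WT replicate 2, and 0.991 for Prnp, without WT replicate 1.

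The second comparison asked which other genes differ between the genotypes. Dag1 (chromosome 9, 108204861 to 108263977), which encodes dystroglycan, a receptor linking cells to the extracellular matrix, fell in APP/PS1 hippocampus by 3.04 on the log2 scale (SE 0.17). It stood at 19.9 ± 4.35 CPM in APP/PS1 and 164 ± 10.5 CPM in WT (SD, n = 3 each), and the highest APP/PS1 library, 24.5 CPM, lay far below the lowest WT library, 156 CPM. With edgeR's quasi-likelihood test its Benjamini-Hochberg adjusted p was 0.0139, and Dag1 was the 1 gene of 18060 to pass. With 1 library fewer, the Dag1 log2 fold change lay between -3.22 and -2.91, but edgeR's adjusted p was 0.176 without WT replicate 1 and 0.0841 without WT replicate 2, so the count of genes past the threshold was 0 in each of those fits, with 371 and 345 genes at an unadjusted p under 0.05. Over all settings tried, adjusted p for Dag1 ran from 2.0e-56 with DESeq2 to 0.176. The count was 6 without APP/PS1 replicate 1, 5 without APP/PS1 replicate 3 and 4 without WT replicate 4. It was 1 with limma-voom and 26 with DESeq2, 13 higher and 13 lower. The 6 were Zfp281, Dag1, Rnf6, Rps27, Rps27rt and Gdf1. Summed CPM differed by only 1.42-fold between libraries for Rps27 with Rps27rt and 1.82-fold for Gdf1 with Cers1. Reads moved between near-identical or overlapping genes are thus not excluded for Rps27, Rps27rt and Gdf1.

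**Figure D1:**
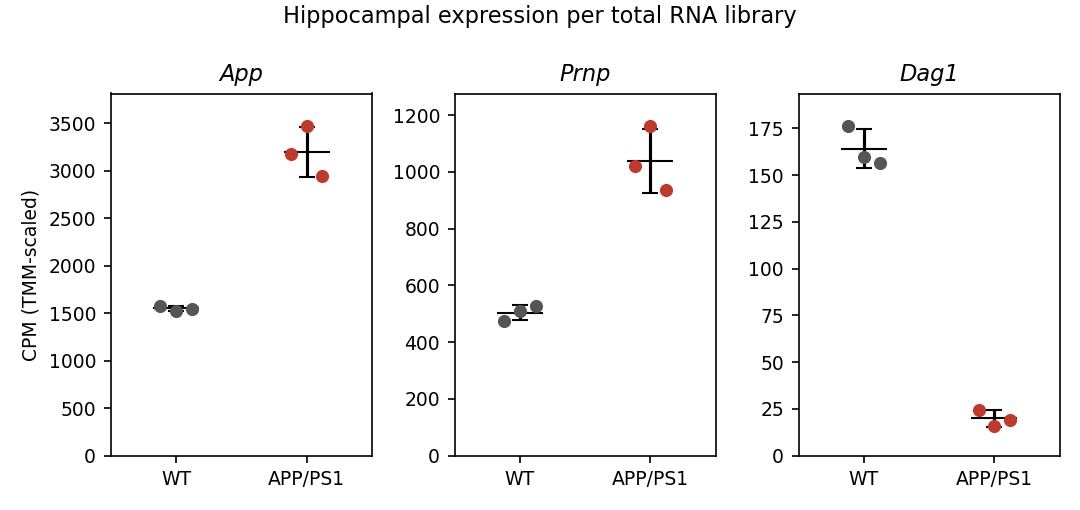
Expression of App, Prnp and Dag1 in CPM of TMM-scaled library size (vertical axes, linear, from 0) in WT and APP/PS1 total RNA libraries; points are libraries, the wide dash is the mean and the bar the SD of 3 libraries. App and Prnp are near 2 times the WT level in all 3 APP/PS1 libraries, and Dag1 is at 15.9 to 24.5 CPM in APP/PS1 against 156 to 176 CPM in WT.

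None of the following genes passed over all genes with edgeR and all 6 libraries, with edgeR's adjusted p of 0.428 for Gm4737 and Gabra3 and 0.887 for the others, and their values are given without a call. DESeq2 called all of them except Mir8113 and Fgf12, quality weights called Gabra3 and Clec2g, and the fit with a surrogate variable called Gabra3 and Fgf12. Among genes with higher values, Hspa5, the endoplasmic reticulum chaperone BiP, stood at 295 ± 16.7 CPM in APP/PS1 and 205 ± 13.6 CPM in WT, and Sdf2l1, another protein of that compartment, at 7.77 ± 0.52 and 5.05 ± 0.05 CPM. Aldh7a1, an aldehyde dehydrogenase of lysine breakdown, had a log2 fold change of 0.60 (SE 0.09), as had 4930402H24Rik. The predicted gene Gm4737 had 1.95 (SE 0.24) and Cdh3, encoding P-cadherin, 1.11 (SE 0.20). Ins2 was at 0.42 ± 0.09 and 0.11 ± 0.01 CPM, and Clec2g had 0 counts in all WT libraries, which makes it at least 4.22-fold higher against a floor of 12 estimated counts over the WT group, or 3 fragments if 1 fragment stands for 4 estimated counts. Among genes with lower values, Gabra3, a GABA-A receptor subunit, stood at 38.4 ± 7.39 CPM in APP/PS1 and 83.9 ± 2.78 CPM in WT, and Mef2c, a transcription factor of excitatory neurons, at 97.7 ± 25.5 and 223 ± 31.9 CPM. Shroom2 had a log2 fold change of -0.95 (SE 0.18), Capza1, encoding an actin-capping subunit, -1.10 (SE 0.22), Dusp26, a phosphatase, -0.56 (SE 0.10), Smyd1 -1.08 (SE 0.23) and Amn -1.33 (SE 0.29). Xlr3b was at 0.03 ± 0.03 CPM in APP/PS1 and 1.09 ± 0.46 CPM in WT, and the miRNA precursor gene Mir8113 at 0.02 and 0.13 CPM, about the level of a few fragments. Without APP/PS1 replicate 3, edgeR's adjusted p was 0.0136 for Gabra3 (log2 fold change -1.30) and 0.0169 for Fgf12 (1.26), a fibroblast growth factor homologue chosen after its values were seen. In all, 617 genes had an unadjusted p under 0.05, 343 higher and 274 lower, where 903 would arise by chance in independent tests. The groups did not overlap for 1877 genes (10.4%), where chance gives 10%.

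The third comparison asked how known cell types and pathways of the hippocampus differ between the genotypes, using the fixed lists. The choroid plexus epithelium list was the most displaced: all 20 members had positive log2 fold changes, with a median of 0.66. Folr1, the folate receptor of this epithelium, had a log2 fold change of 0.59 (SE 0.20), Prlr 0.71 (SE 0.24) and Ttr, which encodes the thyroxine carrier transthyretin, 0.73 (SE 0.29). The unfolded protein response list was higher with a median of 0.25, 13 of 16 members positive, and the heat shock protein list with a median of 0.16, 12 of 14 positive. The immediate early gene list was lower with a median of -0.24, 26 of 30 negative, and so were the neocortex list, with a median of -0.36 and 13 of 15 negative, and the myelin list, with a median of -0.24 and all 19 negative. With camera at the preset correlation, 13 of 35 lists had a Benjamini-Hochberg adjusted p under 0.05, 3 of them higher and 10 lower. With an estimated correlation 0 of the 35 passed, the smallest adjusted p being 0.527, and with fry 0 passed. Without WT replicate 1, 8 lists passed at the preset correlation.

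**Figure D2:**
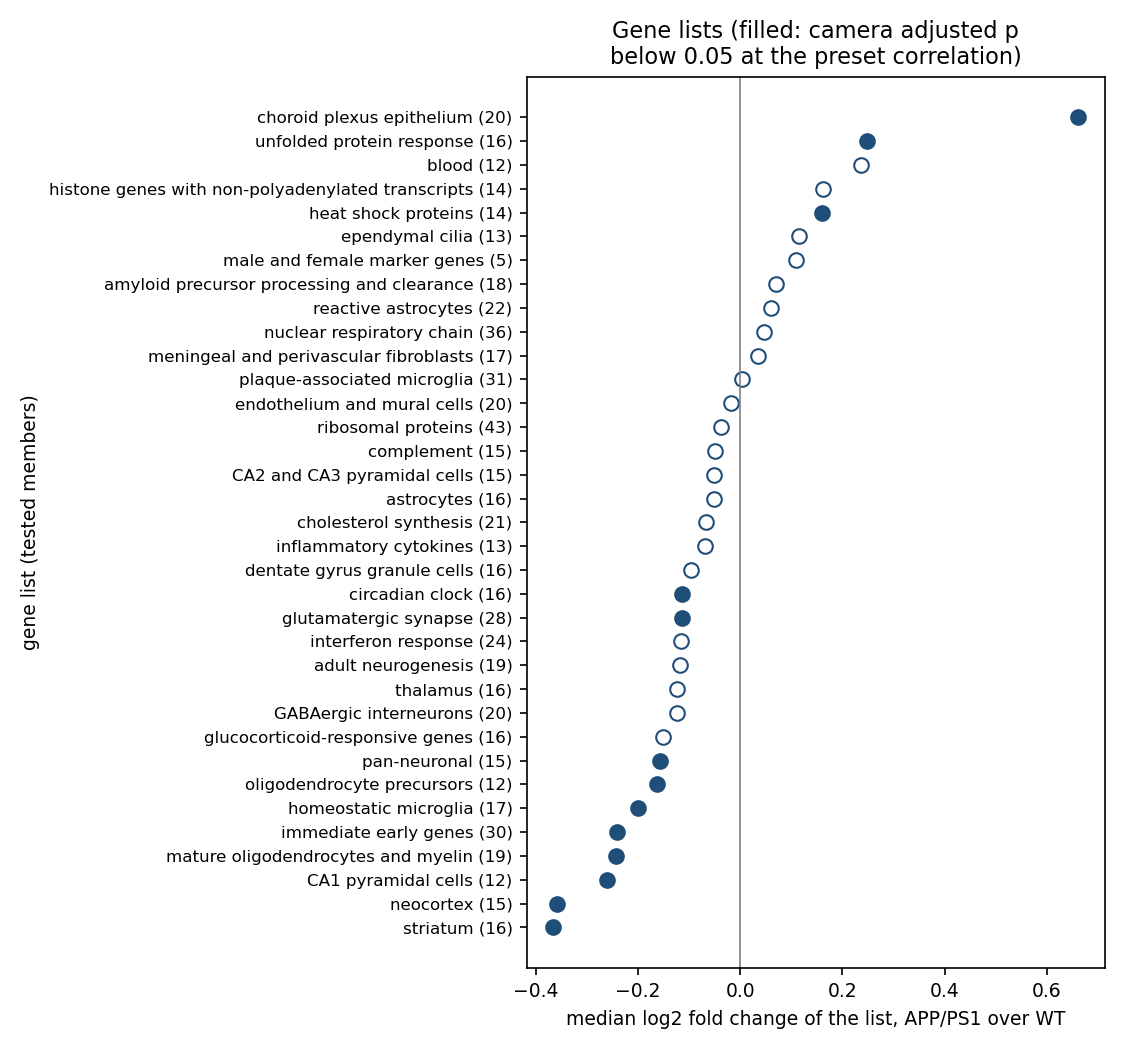
Median log2 fold change (horizontal axis, APP/PS1 over WT) of the 35 tested gene lists (vertical axis, tested members in brackets); filled points have camera adjusted p under 0.05 at the preset correlation and open points do not. The choroid plexus list lies at 0.66 and the unfolded protein response list at 0.25, while the neocortex list lies at -0.36.

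For the choroid plexus list camera's adjusted p was 5.8e-10, and it was adjusted p = 0.527 with an estimated correlation. No member passed edgeR's test over all genes or adjusted over the list alone, although 10 had an unadjusted p under 0.05. The list was highest in APP/PS1 replicate 2, where its median lay 1.02 log2 units above the mean of the other 5 libraries. By the same measure it lay at 0.22 in APP/PS1 replicate 3 and -0.17 in APP/PS1 replicate 1. It lay lower, at -0.41, -0.23 and -0.43, in WT replicates 1, 2 and 4. For each library except APP/PS1 replicate 2, the mean of the others included that high library. Ttr stood at 3481 CPM in replicate 2, 1533 and 2092 CPM in replicates 1 and 3, and 1427 ± 149 CPM in WT. Without APP/PS1 replicate 2 the median of the list was 0.29. Camera's adjusted p was then 4.3e-06 at the preset correlation and 0.552 with an estimated correlation. Ependymal cilia genes, which mark the ventricular lining beside the choroid plexus, had a median of 0.11 with 7 of 13 positive and camera's adjusted p of 0.526, and lay at 0.52 in APP/PS1 replicate 2, the highest of the 6 libraries.

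The unfolded protein response list, the genes that raise folding capacity in the endoplasmic reticulum, had camera's adjusted p of 2.2e-05, and adjusted p = 0.527 with an estimated correlation. Adjusted over the list alone, 2 members passed edgeR's test, Hspa5 (adjusted p = 0.0083) and Sdf2l1 (adjusted p = 0.0092), and over all genes 0 passed with edgeR, while DESeq2 called both. Manf and Xbp1, a secreted neurotrophic factor and a transcription factor of the same response, had log2 fold changes of 0.33 (SE 0.10) and 0.38 (SE 0.13). The heat shock list had camera's adjusted p of 4.7e-04, and adjusted p = 0.527 with an estimated correlation. Adjusted over the list alone, 3 members passed edgeR's test, Hspa5, which both lists hold, Chordc1 (log2 fold change 0.34, SE 0.09) and Hspb1 (0.59, SE 0.16). Both lists stayed past camera's threshold at the preset correlation with each library left out. With an estimated correlation neither passed in those fits, with camera's adjusted p from 0.5516 to 0.7435.

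The immediate early gene list holds transcription factors and effectors induced by neuronal activity. Its camera adjusted p was 6.1e-06, and adjusted p = 0.527 with an estimated correlation, and no member passed edgeR's test over all genes or adjusted over the list alone. Egr1 had a log2 fold change of -0.57 (SE 0.20) and Egr4 -0.69 (SE 0.26), or -0.36 and -0.48 without APP/PS1 replicate 3. The list's median in APP/PS1 replicate 3 lay at -0.72 against the other 5 libraries. By the same measure it lay at 0.13 and 0.02 in APP/PS1 replicates 1 and 2, and at 0.18, 0.15 and 0.16 in WT replicates 1, 2 and 4. The immediate early list stayed past camera's threshold at the preset correlation with each library left out. It passed in none of those fits with an estimated correlation, with camera's adjusted p from 0.5516 to 0.7435. The neocortex list had camera's adjusted p of 6.6e-06, and adjusted p = 0.527 with an estimated correlation. Adjusted over the list alone, Mef2c passed edgeR's test (adjusted p = 0.0135), and Cplx3, a complexin of deep cortical layers, had -0.87 (SE 0.33). The neocortex median was -0.57 without APP/PS1 replicate 2, -0.54 without replicate 1 and -0.24 without replicate 3, past camera's threshold at the preset correlation each time. With an estimated correlation camera's adjusted p was 0.5516, 0.7435 and 0.6549 in these fits.

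The myelin list had camera's adjusted p of 1.5e-05, and adjusted p = 0.527 with an estimated correlation. Opalin, a myelin membrane protein, had a log2 fold change of -0.55 (SE 0.21) and Mobp -0.29 (SE 0.13), and no member passed over all genes or adjusted over the list alone. Without WT replicate 1, the library with the highest myelin values, the list's median was -0.09 and camera's adjusted p 0.062. The CA1 pyramidal cell list had a median of -0.26 (camera adjusted p = 0.0183, and adjusted p = 0.614 with an estimated correlation), with Nr4a1 at -0.48 (SE 0.19) and Ndst3 at 0.81 (SE 0.40), or 0.18 without APP/PS1 replicate 3. The glutamatergic synapse list had a median of -0.12 (camera adjusted p = 0.0183, and adjusted p = 0.614 with an estimated correlation), with Vamp2, a synaptic vesicle protein, at -0.31 (SE 0.12). The pan-neuronal list had a median of -0.16 (camera adjusted p = 0.0206, and adjusted p = 0.527 with an estimated correlation), with Syt1 at -0.56 (SE 0.24) and Tubb3 at -0.24 (SE 0.11). The striatum list, with Rgs9 at -0.48 (SE 0.14) and Syndig1l at -0.56 (SE 0.19), had a median of -0.37 (camera adjusted p = 0.0492, and adjusted p = 0.527 with an estimated correlation). The oligodendrocyte precursor list, with Sox10 at -0.36 (SE 0.16) and C1ql1 at -0.37 (SE 0.19), had a median of -0.16 (camera adjusted p = 0.0492, and adjusted p = 0.614 with an estimated correlation). Circadian clock genes, with Per1 at -0.19 (SE 0.07) and Hlf at -0.24 (SE 0.12), had a median of -0.12 (camera adjusted p = 0.0459, and adjusted p = 0.527 with an estimated correlation). Without APP/PS1 replicate 3 camera's adjusted p at the preset correlation was 0.854 for CA1, 0.409 for the glutamatergic synapse, 0.145 for the pan-neuronal, 0.136 for the striatum and 0.854 for the precursor list. Without WT replicate 1 it was 0.0872 for the glutamatergic synapse, 0.0623 for the pan-neuronal, 0.159 for the precursor and 0.0698 for the striatum list, and without WT replicate 2 it was 0.107 for the precursor, 0.207 for the striatum and 0.0767 for the circadian list. Without WT replicate 4 it was 0.0615 for the glutamatergic synapse, 0.108 for the pan-neuronal and 0.278 for the circadian list, without APP/PS1 replicate 1 it was 0.226 for the striatum and 0.253 for the circadian list, and without APP/PS1 replicate 2 it was 0.0529 for the pan-neuronal and 0.0963 for the circadian list.

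Of 31 tested members of the plaque-associated microglia list, the genes that mark microglia around amyloid deposits, 16 had positive and 15 negative log2 fold changes, with a median of 0.003 and a mean of -0.043. Trem2, a lipid receptor of these cells, had -0.51 (SE 0.18) and Cd52 -0.71 (SE 0.27), while Cst7, an inhibitor of lysosomal proteases chosen after its values were seen, had -0.06 (SE 0.25) at 0.56 ± 0.06 CPM in APP/PS1 and 0.59 ± 0.05 CPM in WT. No member passed edgeR's test, and camera's adjusted p was 0.153, or 0.0348 without WT replicate 4, where the median was -0.06 and adjusted p = 0.642 with an estimated correlation. The homeostatic microglia list had a median of -0.20, 15 of 17 negative, with camera's adjusted p of 0.0375 and adjusted p = 0.689 with an estimated correlation, and without APP/PS1 replicate 3 its median was 0.005 and camera's adjusted p 0.931, with 0.151 without WT replicate 1 and 0.0579 without WT replicate 2. Ptprc in that list had 0.38 (SE 0.16) and Siglech -0.47 (SE 0.25), or -0.24 without APP/PS1 replicate 3. Complement genes had a median of -0.05 and a mean of 0.05, interferon response genes a median of -0.12, and inflammatory cytokines and adhesion molecules a median of -0.07 with Icam1 at 0.70 (SE 0.17) and Il1b at -1.82 (SE 0.52), and none of these 3 lists passed camera with all 6 libraries. Reactive astrocyte genes had a median of 0.06, with Hspb1 at 0.59 (SE 0.16) and Steap4 at 0.93 (SE 0.32), and the general astrocyte list a median of -0.05. Without APP/PS1 replicate 3 camera's adjusted p at the preset correlation was 0.0130 for the interferon response list, with a median of -0.23, and 2.3e-04 for the astrocyte list, with a median of -0.15. With an estimated correlation in the same 5 libraries, adjusted p = 0.691 and adjusted p = 0.572.

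The other lists did not pass camera with all 6 libraries either. Genes that process or clear amyloid precursor had a median of 0.07, with 12 of 18 positive and Adam17, an alpha-secretase, at 0.27 (SE 0.10). Medians were -0.12 for GABAergic interneurons, -0.10 for dentate gyrus granule cells, -0.05 for CA2 and CA3 pyramidal cells, -0.12 for adult neurogenesis, -0.12 for thalamus and -0.02 for endothelium and mural cells. They were 0.03 for fibroblasts of the meninges and vessels, 0.24 for blood, 0.05 for the nuclear respiratory chain, -0.04 for ribosomal proteins, -0.07 for cholesterol synthesis, -0.15 for glucocorticoid-responsive genes, 0.16 for histone genes and 0.11 for sex marker genes. The mean had the other sign for the interneuron list (0.06), dentate gyrus (0.03), adult neurogenesis (0.12), thalamus (0.02), endothelium (0.02) and blood (-0.22), and camera's direction was down for the fibroblast list. In the adult neurogenesis list Neurod1, which the cerebellar list also holds, had 2.15 (SE 0.90) and Eomes, chosen after its values were seen, 1.90 (SE 0.88), and Calb1 in the dentate list had 1.18 (SE 0.56). These values were carried by APP/PS1 replicate 3, where Neurod1 stood at 257 CPM against 29.0 and 26.0 CPM in the other APP/PS1 libraries, Eomes at 21.3 CPM against 2.45 and 2.95 CPM, and Calb1 at 400 CPM against 99.3 and 98.2 CPM. Without that library the log2 fold changes were 0.23 for Neurod1, 0.17 for Eomes and 0.16 for Calb1. The median of the dentate gyrus list was then 0.075 with camera's direction up (adjusted p = 0.0499 at the preset correlation, and adjusted p = 0.691 with an estimated correlation). The interneuron list (median -0.11, adjusted p = 0.0130), the thalamus list (-0.15, adjusted p = 0.0201) and the blood list (-0.81, adjusted p = 0.0202) were lower without it by camera at the preset correlation, and adjusted p = 0.572 for all 3 with an estimated correlation. Without APP/PS1 replicate 2 the preset correlation gave adjusted p = 0.0042 for ribosomal proteins and for cholesterol synthesis and 0.0420 for adult neurogenesis, all lower, and adjusted p = 0.552 for all 3 with an estimated correlation. For ribosomal proteins without WT replicate 1 it gave adjusted p = 0.0442, and adjusted p = 0.723 with an estimated correlation.

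APP/PS1 replicate 3 stood apart from the other total RNA libraries. In it 1914 genes lay over 2-fold from the median of the others, against 644 to 766 in each other library, and its mean correlation with the others was 0.967 across genes, against 0.98 to 0.981. All 27 tested genes of the cerebellar list lay over 2-fold above the mean of the other 5 libraries, with a median log2 difference of 3.36. Among them were Cbln3, a granule cell secreted protein, at 612 CPM against 0.55 CPM, Fat2, a protocadherin of the same cells, at 1327 CPM against 2.61 CPM, and the Purkinje cell genes Pcp2, at 163 CPM against 0.49 CPM, and Car8, at 733 CPM against 5.20 CPM. In the same library the hippocampal lists were lower, with median log2 differences of -0.78 for dentate gyrus, -0.80 for CA1 and -0.62 for CA2 and CA3. The immediate early, neocortex and homeostatic microglia lists were lower there too, at -0.72, -0.71 and -0.60. The blood list was higher there, at 1.43, with 7 of 12 members above 1 and 2 below -1. In the other libraries its median ran from -0.72 to 0.65. Of the list of medulla, pons and spinal cord genes 4 were tested, with a median of -0.27 there and of -0.46 to 0.54 in the other libraries.

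**Figure D3:**
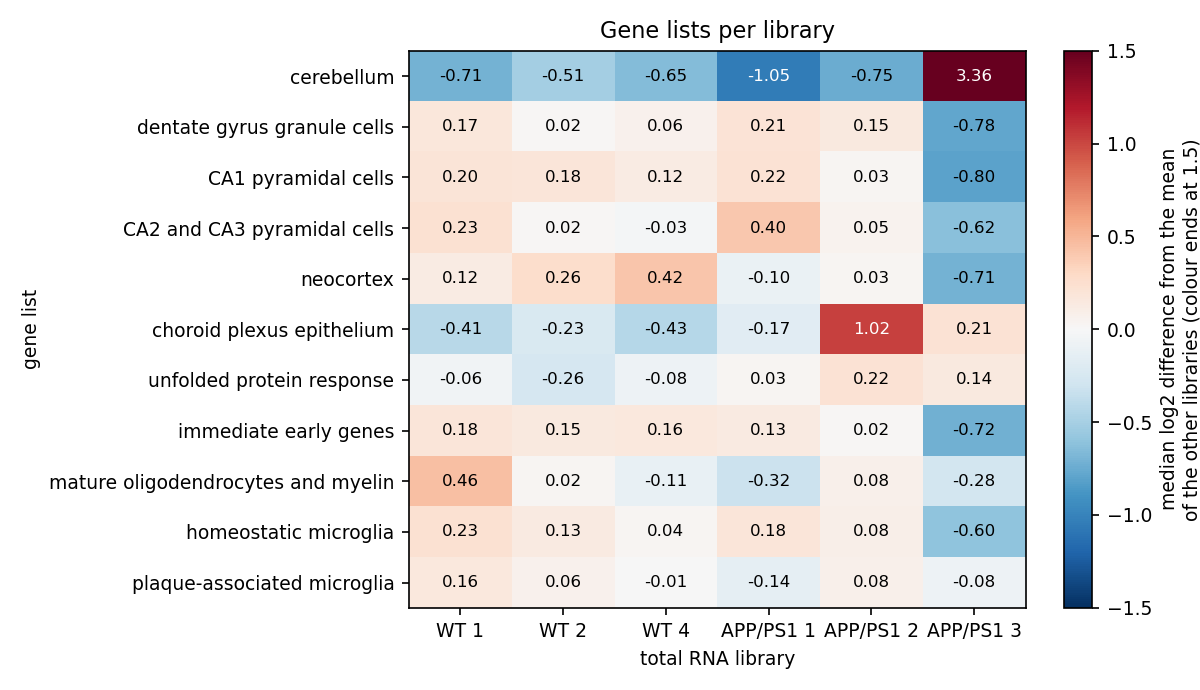
Median log2 difference of each gene list (vertical axis) in each total RNA library (horizontal axis) from the mean of the other 5 libraries, as colour and number; colours end at 1.5 in either direction. The cerebellum list, added after seeing the data, lies at 3.36 in APP/PS1 replicate 3 and at -0.51 or lower elsewhere, and the choroid plexus list at 1.02 in APP/PS1 replicate 2.

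The fourth comparison asked which mature miRNAs differ between the genotypes. The expression of miR-206-3p, known from skeletal muscle and cerebellum, stood at 643 CPM in the column headed APP3 and 3.09 to 6.54 CPM in the other 5 columns. Both miR-10 family members named here, encoded within the Hox clusters, were high in 2 of 3 APP/PS1 columns. The counts of miR-10b-5p stood at 178 and 182 CPM in the columns headed APP2 and APP3, 9.78 CPM in APP1 and 12.8 ± 5.45 CPM in WT, and those of miR-10a-5p at 107, 93.1 and 9.85 CPM in the same columns and 14.3 to 18.2 CPM in WT. The activity-induced miR-132-5p stood at 916 ± 127 CPM in APP/PS1 and 1235 ± 105 CPM in WT (SD, n = 3 each), a log2 fold change of -0.43 (SE 0.16), and miR-132-3p at 971 ± 103 and 1225 ± 30.7 CPM, a log2 fold change of -0.33 (SE 0.14). The choroid plexus miRNAs miR-448-3p and miR-1912-3p had log2 fold changes of 0.52 (SE 0.23) and 0.71 (SE 0.25). With edgeR's quasi-likelihood test 0 of 703 miRNAs had a Benjamini-Hochberg adjusted p under 0.05, the smallest adjusted p being 0.958. DESeq2 and limma-voom also called 0, and 25 miRNAs had an unadjusted p under 0.05, 13 higher and 12 lower, where 35.1 would arise by chance. Without the column headed APP1, 3 miRNAs passed, miR-10a-5p, miR-10b-5p and miR-615-3p, the last chosen after its values were seen.

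**Figure D4:**
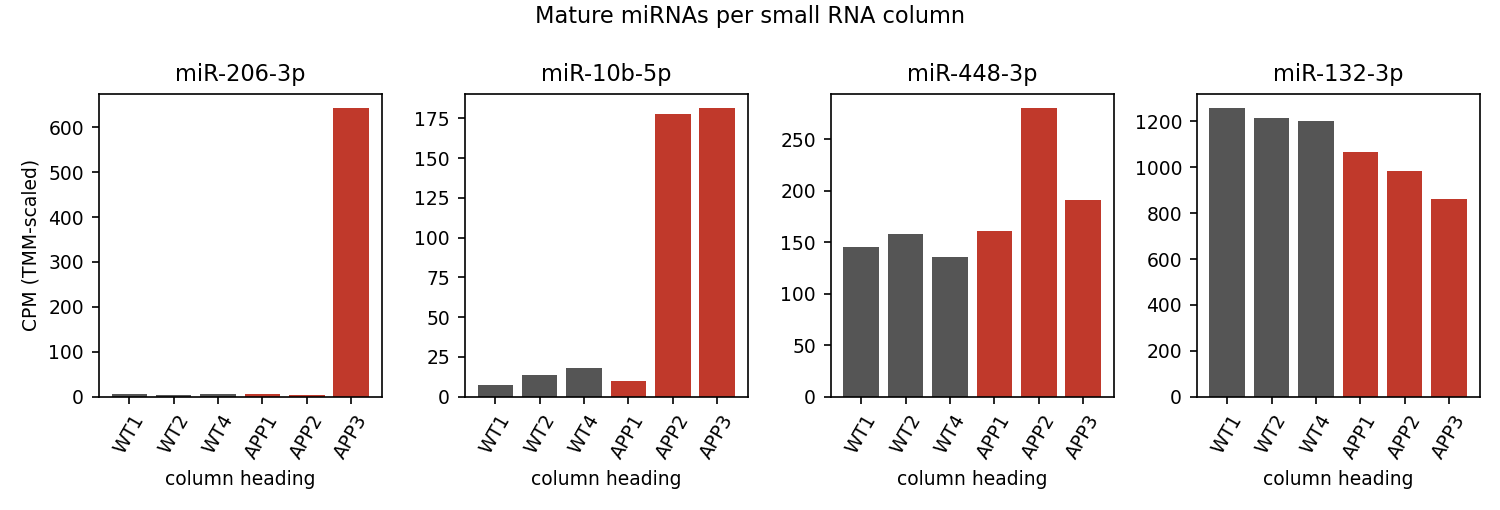
CPM of TMM-scaled library size (vertical axes, linear, from 0) of 4 miRNAs in each small RNA column (horizontal axis), WT in grey and APP/PS1 in red. The bar of miR-206-3p reaches 643 CPM in the column headed APP3 alone, miR-10b-5p is high in the columns headed APP2 and APP3, miR-448-3p is highest in APP2, and miR-132-3p lies lower in all 3 APP/PS1 columns.

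Among other miRNAs with higher values, miR-29b-1-5p had a log2 fold change of 0.84 (SE 0.24), miR-547-3p 0.99 (SE 0.40) and miR-320-3p 0.81 (SE 0.34). Without the column headed APP3 the log2 fold changes of miR-547-3p and miR-320-3p were 0.40 and 0.31. Among those with lower values, miR-1258-3p had -2.04 (SE 0.65), miR-3968 -0.64 (SE 0.21), miR-3963 -1.14 (SE 0.45) and miR-7236-3p -0.81 (SE 0.33). In the miR-200 family, known from epithelia and sensory tissue, miR-200a-3p was at -0.70 (SE 0.27), miR-200a-5p at -0.86 (SE 0.30) and miR-429-3p at -0.92 (SE 0.31). Of the same family, miR-200b-3p was at -0.34 (SE 0.28) and miR-200c-3p at 0.40 (SE 0.32), both chosen after their values were seen. The list of choroid plexus and ependymal miRNAs was higher with a median of 0.50, 9 of 10 positive, with camera's adjusted p of 6.1e-04 and adjusted p = 0.711 with an estimated correlation. The activity-responsive list was lower with a median of -0.18, 8 of 9 negative, with camera's adjusted p of 0.0275 and adjusted p = 0.711 with an estimated correlation. No member of either list passed edgeR's test over all miRNAs or adjusted over the list alone. Without the column headed APP2, camera's adjusted p was 0.245 for the choroid plexus list, whose median was then 0.25, and 0.222 for the activity-responsive list, and without the column headed WT2 it was 0.169 for the latter. Without the column headed APP1, 4 miRNA lists passed, the endothelial list (adjusted p = 0.0090) and the thalamus, hypothalamus or sensory ganglia list (adjusted p = 0.0466) among them. With an estimated correlation in the same 5 columns 0 passed, and adjusted p = 0.401 for both of these lists.

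The other 7 miRNA lists did not pass camera with all columns. Medians were -0.05 for inflammatory and myeloid miRNAs, with miR-146b-5p at 0.49 (SE 0.23) and miR-146a-5p at 0.35 (SE 0.21), -0.08 for neuronal miRNAs, -0.01 for miRNAs reported in Alzheimer's disease and -0.13 for oligodendrocyte miRNAs, where all 7 were negative. They were 0.07 for endothelial miRNAs, 0.14 for blood miRNAs and 0.40 for miRNAs of thalamus, hypothalamus or sensory ganglia. Without the column headed APP3, camera's direction turned from up to down for the last 2 of these lists. In the last list miR-182-5p, miR-183-5p and miR-96-5p, chosen after their values were seen, were then at -0.02, -0.25 and -0.42. With all columns they were at 1.88, 1.55 and 1.74, while miR-10a-5p was at 2.13, or 1.91 without that column. Adjusted over the list alone, miR-10b-5p in the endothelial list passed edgeR's test (adjusted p = 0.0375). The mean had the other sign for the inflammatory list (0.06) and the Alzheimer's disease list (0.10). The column headed APP3 stood apart here as well, with 66 miRNAs over 2-fold from the median of the other columns, against 4 to 17 in each other column. In that column miR-195a-5p stood at 1319 CPM against 193 to 238 CPM elsewhere, and miR-486a-5p, from the blood list, at 1065 CPM against 161 to 208 CPM. Of the same list miR-451a had a log2 fold change of 0.12 (SE 0.28) and miR-144-3p -0.23 (SE 0.32), both chosen after their values were seen.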

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

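Quality weights (also in camera, with 9 gene lists, 7 of the 13 and 2 others, astrocytes and glucocorticoid-responsive genes), division by 4 and fry and the block on the miRNA lists were chosen after seeing the data. The mRNA count of 1 gene held with RLE factors, library size alone, no filter, the stricter filter, limma-voom and values divided by 4. It was 26 with DESeq2, 5 with quality weights, 153 at an unadjusted p under 0.05 with a 2-fold change, 5 with a surrogate variable, and 0 to 6 with 1 library left out. The App log2 fold change was 1.04 with DESeq2, 1.1005 with quality weights and 1.0951 with the surrogate variable, past the threshold in each, and 0.98 to 1.09 with 1 library left out. The Prnp log2 fold change was 1.04, 1.1088 and 1.1072 in the same settings, past the threshold in each, and 0.96 to 1.11 with 1 library left out. The Dag1 log2 fold change ran from -3.22 to -2.91 with 1 library left out. The 13 gene lists became 0 with an estimated correlation, 0 with fry, 8 with quantile normalization and 8 to 14 with 1 library left out, or 0 there with an estimated correlation. It was again 13 without APP/PS1 replicate 3, made of 7 of the first 13 and 6 others. The count of 0 miRNAs became 5 without the filter, where miR-615-3p and miR-7688-5p joined miR-10a-5p, miR-10b-5p and miR-206-3p, 5 at the unadjusted threshold and 0 to 3 with 1 column left out. The 2 miRNA lists became 0 with an estimated correlation, 0 with fry and 0 to 4 with 1 column left out, or 0 there with an estimated correlation. Of 111 named features 7 changed sign somewhere, in 12 of 1734 values. In the block fits, number 3 marked 1 APP/PS1 library or column and number 4 marked 1 WT library or column. These added nothing to the genotype difference, which rested on the libraries or columns numbered 1 and 2. With the replicate block Calb2 was at -0.065, 2 genes passed, Rprl3 and Dag1, and 12 gene lists passed, 6 of the 13 and 6 others, with plaque-associated microglia (adjusted p = 0.0478), interferon response (0.0239), astrocytes, interneurons, fibroblasts and thalamus gained and homeostatic microglia (0.626) and immediate early genes (0.0573) lost. With the number in the column heading as a replicate block 0 miRNAs passed, with 71 at an unadjusted p under 0.05, and 1 miRNA list, with the activity-responsive list lost (adjusted p = 0.112). In that fit the mmu-miR-206-3p log2 fold change was -0.0046, with miR-195a-5p at -0.020 and miR-486a-5p and miR-486b-5p at -0.26. Numbers 1 and 2 alone are shared, with r = 0.094 and -0.043 for total RNA and 0.219 and 0.246 for small RNA. Other pairings across genotypes ran from -0.082 to 0.068 for total RNA and from -0.206 to 0.172 for small RNA. The shared numbers were thus the 2 highest for small RNA but not for total RNA. They are not shown to pair mice, and a shared effect of the number is not excluded. With the surrogate variable miR-486a-5p and miR-486b-5p were at -0.20. With 1 library left out the homeostatic microglia median ran from -0.325 to 0.005, miR-206-3p from -0.075 to 5.99, miR-486a-5p and miR-486b-5p from -0.24 to 1.65, miR-145a-5p from -0.012 to 0.49 and miR-338-3p from -0.26 to 0.016, with the sign changed without APP/PS1 replicate 3 for the first, without the column headed APP3 for the next 3 and without the column headed WT1 for the last 2. The signs of miR-206-3p, miR-486a-5p and miR-486b-5p turned on the column headed APP3. They changed where it was left out or had its own block number. The surrogate variable, which also changed the sign of the last 2, stood at 0.911 in that column and at -0.217 to -0.125 in the others. For miR-206-3p that column held 643 CPM, against 3.09 to 6.54 CPM in the others. The cause of the other sign changes was not tested. Fewer libraries did not always give fewer genes at an unadjusted p under 0.05 in edgeR's test. Their number was 617 with all total RNA libraries. It was 1501, 973 and 737 without APP/PS1 replicates 1, 2 and 3, and 371, 345 and 360 without WT replicates 1, 2 and 4. The seed-site test was not run, nor were the alternatives for normalized values, since both tables hold counts. With 3 mice per genotype, and dispersions fitted with APP/PS1 replicate 3 included, the simulated recovery of 35% of 2-fold changes limits what could be called.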

Other observations

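The tests below were chosen only after the result was seen, except the splits of the libraries. Some signals were strongest in single libraries. The choroid plexus signal of APP/PS1 replicate 2, 2.04-fold over the other libraries at the list's median, had a counterpart in the small RNA column headed APP2, where the list of choroid plexus and ependymal miRNAs lay at a median of 0.75 log2 units above the mean of the other columns, although no label ties that column to the same mouse. Of its 10 members 9 were above, up to 0.99 for miR-1912-3p, and miR-449a-5p was at -0.13. Xist, the transcript of the inactive X chromosome, was at 1.79 to 2.90 CPM and Ddx3y, a Y-linked gene, at 79.9 to 109 CPM in all 6 total RNA libraries, so each library showed male expression.

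APP/PS1 replicate 3 differed from the other 5 total RNA libraries, and cerebellar tissue in that sample is a candidate explanation, since the cerebellar list lay at a median of 3.364 log2 units above the others, 17 of its 27 tested genes being at 1 CPM or more in the other libraries and 2 being in other lists, with Itpr1 at 3570 CPM against 824 CPM and Fat2 at 1327 CPM against 2.61 CPM. A library wholly from another region is argued against by the 43 hippocampal list genes, which were lower by a median of only -0.77, that is 58.6% of the other libraries, with -2 as the bound. Mixing within 1 sequencing library alone is argued against by the small RNA column of the same name, in which the number of miRNAs over 2-fold away was 3.88 times the next highest, a count that replaced, after a first run, the median of 3 miRNAs picked for being high there (2.626, read the same way), although no label ties that column to the same mouse. A genotype effect is argued against by the other APP/PS1 libraries, in which the cerebellar list had a median log2 fold change of -0.199. Dissection and mixing of tissue or RNA before the libraries were made remain open.

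The fall of Dag1 was seen in all 3 APP/PS1 libraries. Reads moved to any single one of the 39 tested genes within 500 kb are argued against. The largest gain among them, in Rnf123, was 14.4% of the 144 CPM that Dag1 lost. Reads assigned to a more distant gene, or to none, would not be seen this way. The loss of 1 of 2 gene copies by itself would leave a log2 fold change near -1, against the -3.044 observed, and the tissue makeup of replicate 3 is argued against by the -3.025 without it. Within 5 Mb, 6.92% of 159 genes had an unadjusted p under 0.05 in edgeR's test (exact 95% interval 3.5 to 12%), against 3.38% elsewhere. The interval lies above the share elsewhere, but it treats neighbouring genes as independent. The bound asked for, chosen after the result was seen, was 3 times the share elsewhere. That bound lies inside the interval, so altered expression across the segment stays open. A strain variant carried with the transgene, a change at Dag1 itself, reads assigned elsewhere and a response to the transgene were not tested and may each apply.

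Some genes were near 0 in some libraries and abundant in the others, and reads moved between near-identical or overlapping genes could explain part of this. For 3 of 7 pairs picked for this pattern, the pair's summed CPM differed by under 2-fold between the highest and lowest library, namely Rps27 with Rps27rt (1.42-fold), Gdf1 with Cers1 (1.82-fold) and Evi2 with Evi2b (1.94-fold), where single members differed by up to 49.4-fold. For Hba-a1 with Hba-a2 the sum still differed by 2.2-fold, and for the Hbb, Zfp965 and Dynlt1c pairs by 5.69-fold or more. Reads moved to a gene outside the pair would not be seen in these sums, so the unequal sums do not count against such movement. With 7 pairs the explanation cannot be told apart from others for the pattern as a whole, a reading set after a first run, in which a plain majority of pairs was asked for and the same 3 of 7 counted against it.

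The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For mRNA the real split gave 1 gene and the highest other split 7, and 6 of 10 splits gave at least 1. For gene lists the real split gave 13 and the highest other 17, with 3 of 10 splits giving as many, and for miRNA lists 2 against 3, with 4 of 10. For miRNAs all 10 splits gave 0. The split with 7 genes set APP/PS1 replicates 1 and 3 with WT replicate 2 against the rest, and the source of these differences is unknown. Btg3 and Gm7334, both among the 7, ran opposite to each other. Where Btg3 was at 10.1 to 15.6 CPM, Gm7334 was at 0. Where Btg3 was at 0.007 to 0.016 CPM, Gm7334 was at 14.8 to 16.6 CPM. Dynlt1c, another of them, is in a pair above whose sum differed by 5.69-fold. Reads moved between genes were not tested for the 7 as a set. Of these 7 genes 3, Btg3, Gm7334 and Dynlt1c, had a mean under 0.1 CPM in 1 of the sets, and the other 4 did not, with Pja1 at 156 CPM against 59.6 CPM, Taf9b at 23.7 CPM against 10.01 CPM, Tgfbrap1 at 74.4 CPM against 36.9 CPM and Gxylt1 at 34.6 CPM against 7.86 CPM.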
